A study of Mus musculus with 15 samples.

How the data were processed

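Livers of mice were profiled by RNA sequencing in 15 libraries, 5 from young control mice, 5 from aged control mice and 5 from mice given KSL0608-Se and irradiation. KSL0608-Se is a compound known here only by its code name, and the series describes a light-activated removal of senescent cells. The labels give the tissue, the group and a replicate number. They give no ages, sex, strain, dose, light setting or processing date, and the age of the treated mice is not stated. The groups are called young, aged and treated from here on. Nothing in the labels says that each library came from a separate animal, so p-values measure the spread between these libraries, which may in part be technical.

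Total RNA was extracted with TRIzol, treated with DNase and checked for quality, per the labels' protocols. The authors trimmed reads with fastp, aligned them with HISAT and estimated expression with RSEM on GRCm39, per the submitters' processing notes, which state no versions or settings. The deposited values are TPM, a measure of transcript share which the authors scaled within each library for gene length and total and gave to 2 decimals. TPM keeps no sequencing depth, so the depth of each library is unknown, no counting interval or detection floor was computed, and a value of 0 is described as listed at 0. The table holds 55849 gene rows, of which 1836 have no symbol and 435 are models assembled from reads. Each library sums to between 999999 and 1000000 TPM. The table also has 3 columns of group means, which equalled the means of the library columns and were not used. The reference annotation at hand was GENCODE M21 on the older build GRCm38. It was therefore used only for gene types and for which genes lie at the same place, and 52081 of the table's identifiers were found in it. Coordinates are not used here.

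Expression was analysed on the log2(TPM + 1) scale, for 12168 genes with a mean of at least 1 TPM over the 15 libraries. Fold changes on this scale understate the change of genes with low values. All 3 groups entered a single linear model in limma 3.58.1 (R 4.3.3), with moderated variances, a trend on mean expression and robust estimation. The 3 contrasts were aged against young, treated against aged and treated against young. P-values were adjusted over all tested genes by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called. These choices, the gene lists and the rule for naming genes were fixed before the data were examined.

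The 47 gene lists cover senescence, inflammation, cell types of the liver and of blood, zonation, metabolism and sex-biased liver genes. Of their 1256 symbols, 1239 were in the table and 1073 were tested. Counts of list members below refer to tested members only. The others lay under the filter of 1 TPM or were not in the table. The filter uses the mean over all 15 libraries, so a gene high in 1 library can pass it. Lists were tested against the other genes with camera at a preset correlation between genes of 0.01, adjusted over the 47 lists. Camera with an estimated correlation and the fry test served as alternatives. Fry asks whether the genes of a list move, on balance, in 1 direction, and does not compare the list with other genes. For each list, the number of called members is given as adjusted over all genes and as adjusted over the list alone.

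Named genes followed a fixed rule. Cdkn1a, Cdkn2a, Glb1 and Lmnb1 are named in every comparison. For each comparison, the rule takes the 8 largest rises and the 8 largest falls among called genes whose groups do not overlap in any library and whose higher group averages at least 5 TPM. Predicted genes and immunoglobulin variable segments are excluded. Up to 4 members with the smallest p are named per list described. Called genes whose groups did not overlap numbered 123 for aged against young. Over all genes tested, the groups did not overlap in 3.38% for aged against young and in 0.69% for treated against aged, against the 0.794% that chance gives with 5 against 5.

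Whether treatment moved age-changed genes back was measured in 3 ways. The first counts genes called in both contrasts with opposite signs. The second is the covariance, across genes, of the aged-minus-young and treated-minus-aged changes. Both changes share the aged libraries, so 100 sets of unchanged groups were simulated with the residual spread and correlation of the data, and the aged libraries were also split into separate sets. The last is the share of the age difference regained. For each of 100 splits, 3 aged and 3 young libraries selected the 200 genes with the smallest p, and the other aged and young libraries set the values 0 and 1. Treated libraries were compared on this scale with aged libraries held out of both steps, by a two-sided permutation test. In that comparison fewer aged libraries selected the genes. Each aged value came only from the fits that held it out, and each treated value from all fits. The aged values also depend on one another, so the p and the interval of this test are approximate.

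The procedures were tested on simulated data with the means and spread of the 12168 genes. The noise was drawn independently for each gene, without the correlation between genes or the outlying libraries of the real data. The rates below may therefore not hold for these libraries. For treated against aged, 70.0% of genes changed by 1 on the log2 scale and 93.0% of those changed by 2 were recovered, with 8 false calls, or 4.68% of all calls. The share measure returned 0.00382, 0.496 and 1.00 for simulated shares of 0, 0.5 and 1.

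Alternatives were pseudocounts of 0.1 and 5, no filter, a filter at 5 TPM, quantile normalization, median-ratio scaling, rescaling without mitochondrial and haemoglobin genes, fits of the compared groups alone, a replicate block, library weights, moderation without trend or robust estimation, a minimum change of 1 on the log2 scale, and leaving out each of the 15 libraries. Leaving out young 4, aged 5 and treated 1 together was added after the data were seen. Near-identical genes, such as the Mup, Cyp3a, Cyp2d, Cyp2b, Cyp4a, Hsd3b, Serpina1 and Sult2a families, histone genes and immunoglobulin genes, share reads, and the table does not say how these were divided. Values of single members of these families are therefore uncertain. The strand of the libraries is not given in the sources used here. Figures were drawn with matplotlib.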

Results

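RNA was measured in 15 libraries of mouse liver, 5 per group, to compare aged with young control livers and to ask whether a light-activated senolytic treatment moved liver expression toward the young state. On average 18309 ± 352 genes had a value above 0 in young livers, 19206 ± 604 in aged and 19596 ± 1094 in treated livers (SD, n = 5 each). The 10 most abundant genes held 29.6 ± 2.5% of TPM in young, 27.0 ± 2.79% in aged and 26.8 ± 3.38% in treated livers. Sequencing depth is unknown for these values. All 15 libraries had Xist at 7.39 TPM or more and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty at no more than 0.08 TPM. Pearson's r between libraries of a group, across genes, ranged from 0.907 to 0.975.

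**Figure D1:**
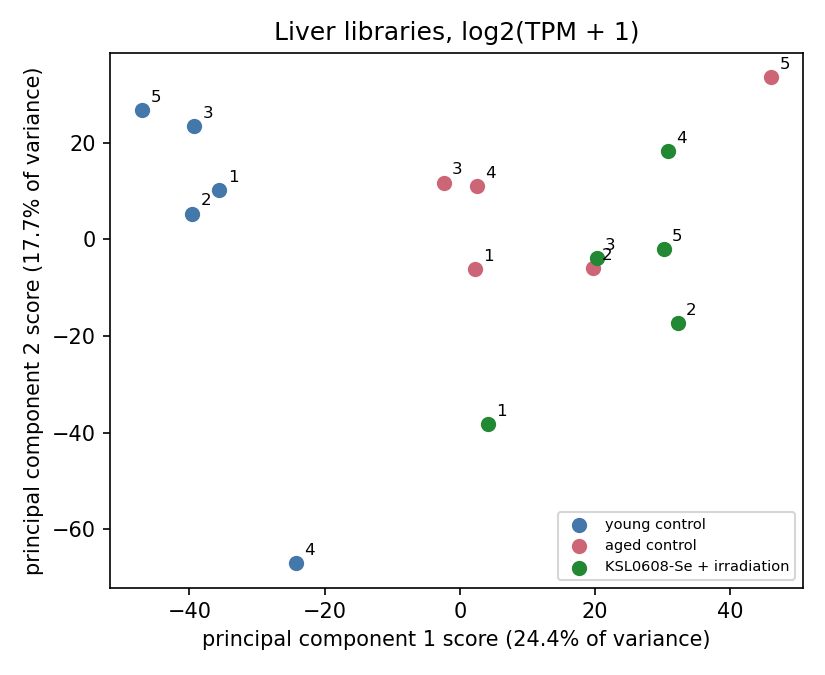
Principal component scores of the 15 liver libraries from log2(TPM + 1) of 12168 genes, with component 1 (24.4% of variance) on the x axis and component 2 (17.7%) on the y axis. Points are libraries, numbered by replicate and coloured by group. Young libraries lie at the left, aged and treated libraries overlap at the right, and young 4 lies apart at −67.1 on component 2.

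The largest changes of single genes between aged and young livers were in liver genes with sex-biased expression, Mup genes and immunoglobulin genes. A1bg, a secreted plasma glycoprotein made by female mouse liver, averaged 3955 ± 1695 TPM in aged and 20.6 ± 13.0 in young livers (SD, n = 5 each), a rise of 7.61 on the log2 scale (SE 0.42, limma adjusted p = 1.45e-07). The major urinary protein gene Mup15 rose by 8.01, Mup17 by 6.43 and Mup19 by 5.10. These genes encode secreted pheromone carriers. The cytochrome P450 genes Cyp3a44 and Cyp3a16 rose by 5.65 and 5.54, and the immunoglobulin constant-region genes Ighm and Igkc by 5.83 and 5.82. Cyp2d9, a steroid hydroxylase typical of male liver, fell from 68.8 ± 24.0 to 4.04 ± 1.24 TPM (log2 change −3.75, adjusted p = 4.53e-06).

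In all, 132 of 12168 genes were called by limma, 113 higher and 19 lower in aged livers, and 1061 had an unadjusted p under 0.05 against 608.4 by chance. The other falls were smaller. Eif4ebp3, an inhibitor of cap-dependent translation, fell by 2.53, and Cdh1, which encodes the adhesion protein E-cadherin, by 2.16. The retinol dehydrogenase gene Rdh9 fell by 1.77, Smim22 by 1.75, Ociad2 by 1.73, the steroid dehydrogenase gene Hsd3b3 by 1.39 and Enho, which encodes the peptide hormone adropin, by 1.35. Leaving out single libraries ended some of these calls, for Cdh1 and Ociad2 in 10 of 15 cases (highest adjusted p 0.109 and 0.112), for Enho in 7 (0.0957) and for Hsd3b3 in 5 (0.0563). The count fell to 79 without young 3. The direction split depended on scaling, with 78 genes higher and 41 lower after quantile normalization and 96 higher and 33 lower with median-ratio scaling. With young 4, aged 5 and treated 1 left out together, a choice made after seeing the data, 190 genes were called, 132 of them higher.

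**Figure D2:**
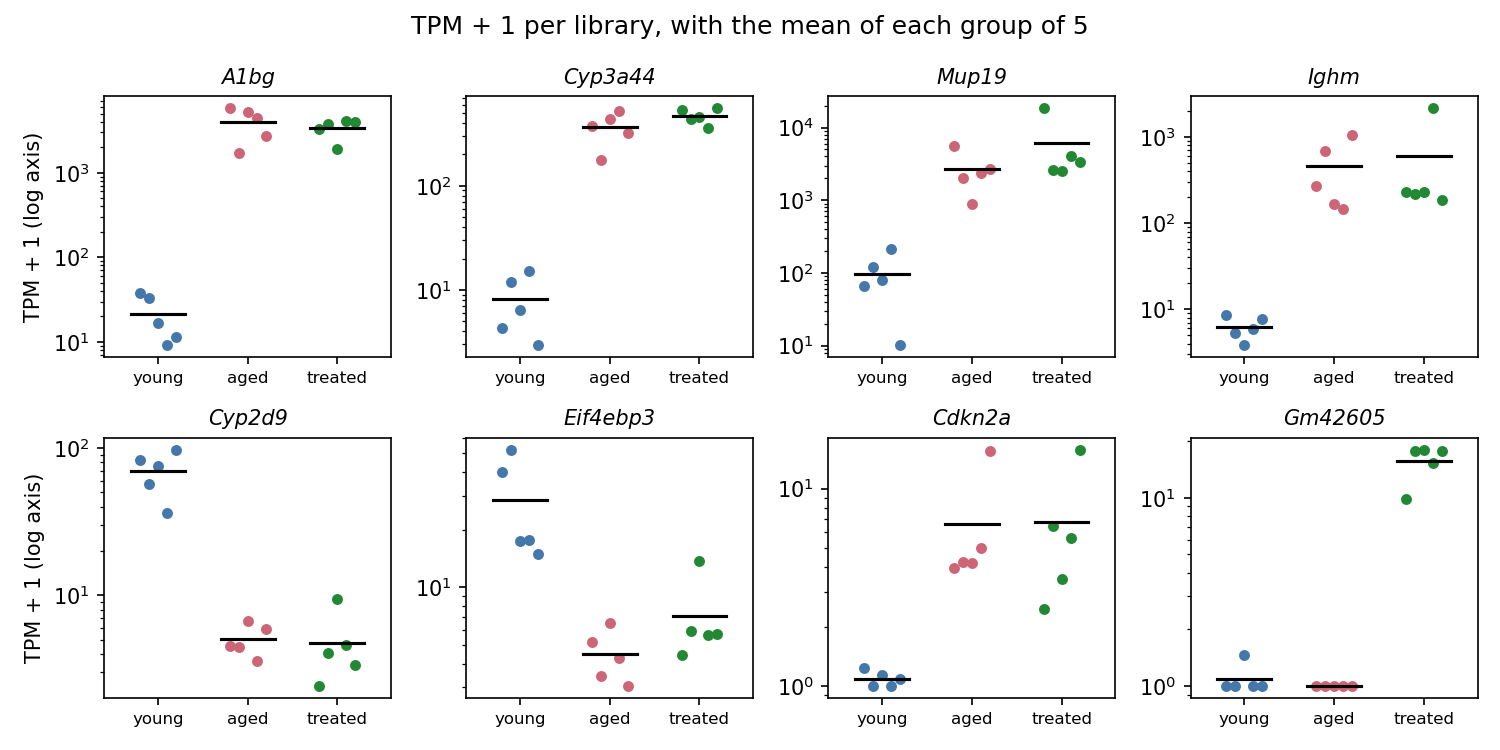
TPM + 1 of 8 genes on a log axis, by group on the x axis. Each point is a library (n = 5 per group) and each bar the group mean. A1bg, Cyp3a44, Mup19 and Ighm were higher and Cyp2d9 and Eif4ebp3 lower in aged and treated than in young livers, and Gm42605 was above 8 TPM in the treated libraries alone.

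Markers of senescence were mixed. Cdkn2a, which encodes the cell-cycle inhibitor p16 and the tumour suppressor Arf, rose from 0.09 ± 0.098 to 5.60 ± 5.04 TPM (log2 change 2.37, SE 0.44, adjusted p = 0.0114). It was higher in each of the 5 aged libraries than in any young one, and aged 5 at 14.6 TPM lay far above the other aged libraries at 2.97 to 4.01. With a pseudocount of 5 this call ended (log2 change 0.96, adjusted p = 0.229). The adjusted p ranged from 0.000104 with a pseudocount of 0.1 to that value over the alternatives that tested Cdkn2a. The filter at 5 TPM drops this gene. Cdkn1a, another cell-cycle inhibitor, stood at 20.1 ± 6.56 against 36.1 ± 19.4 TPM (adjusted p = 0.755). The lysosomal galactosidase gene Glb1 stood at 10.6 ± 1.27 against 10.2 ± 2.61 TPM (log2 difference 0.09). Lmnb1, a nuclear lamina gene, stood at 5.03 ± 4.60 against 2.37 ± 0.81 TPM (log2 difference 0.63, adjusted p = 0.653), with aged 5 at 13.16 TPM and the other aged libraries at 2 to 3.98, and without aged 5 the log2 difference of Lmnb1 was 0.26. The list of 16 markers expected to rise with senescence was not called (median 0.13, camera adjusted p = 0.0682). The 12 markers expected to fall, Lmnb1 among them, were called in the other direction, higher in aged livers (median 0.46, camera adjusted p = 0.016, and adjusted p = 0.661 with an estimated correlation). None of these 12 passed alone or adjusted over the list alone. Aged 5 carried this call, and without it the median was 0.05 (adjusted p = 0.75). The call also ended with library weights (0.127) and without young 4, aged 5 and treated 1 together (0.894). This list shares genes with the cell cycle list described below, so the calls of both are not independent. Among 40 secreted senescence factors, Igfbp5 rose (log2 change 1.15), Igfbp2 fell (−1.20, from 569 ± 163 to 239 ± 13.2 TPM) and 38 did not pass. Adjusted over the list alone, 3 rose and 1 fell. The list as a whole was called higher by camera (median 0.29, adjusted p = 0.0101), with adjusted p = 0.622 with an estimated correlation. This call ended without aged 5 (adjusted p = 0.0552), without aged 2 (0.0684) and with a filter at 5 TPM (0.202), and without young 4 the median was 0.19. The Igfbp5 call ended in 7 of 15 fits without 1 library (highest adjusted p 0.074).

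Genes of immune cells were higher in aged livers as groups. All 23 tested markers of B and plasma cells had higher means, with a median log2 difference of 1.27 (camera adjusted p = 7.85e-15, and adjusted p = 0.464 with an estimated correlation). Of these, Ighm, Igkc and Jchain, which encodes the joining chain of secreted antibodies, rose. Adjusted over the list alone, 12 rose. Igkc averaged 1162 ± 1452 TPM in aged and 11.2 ± 3.83 in young livers, and Jchain 40.8 ± 49.9 against 0.414 ± 0.171. The Jchain call ended in 12 of 15 fits without 1 library (highest adjusted p 0.0892). All 24 monocyte and macrophage markers had higher means (median 0.76, camera adjusted p = 6.32e-10, and adjusted p = 0.549 with an estimated correlation). Only Trem2, a lipid receptor of macrophages, passed (log2 change 1.45), and 5 rose adjusted over the list alone. Without young 1, Trem2 had an adjusted p of 0.0515. Lyz2, a lysozyme gene of myeloid cells, stood at 258 ± 171 against 72.9 ± 26.7 TPM (adjusted p = 0.103). Of 12 genes of MHC class II presentation none passed alone, and 9 rose adjusted over the list alone. Cd74 stood at 414 ± 345 against 147 ± 74.4 TPM and H2-Eb1 at 133 ± 118 against 39.8 ± 19.3. The list median was 1.15 (camera adjusted p = 4.88e-08, and adjusted p = 0.549 with an estimated correlation). The 19 markers of T and NK cells had a median of 0.80 (camera adjusted p = 3.27e-06, and adjusted p = 0.622 with an estimated correlation), and none passed alone or adjusted over the list alone. Aged 5 stood apart in both lists. Its mean over the T and NK cell markers was 3.43 on the log2 scale, while aged 1 and aged 4 at 1.05 and 1.12 lay near the young libraries at 0.90 to 1.08. Without aged 5 the medians were 0.46 for T and NK cells (adjusted p = 0.00484) and 0.76 for MHC class II (adjusted p = 1.22e-06). The T cell chemokine gene Ccl5 stood at 69.8 ± 89.7 against 7.31 ± 2.03 TPM. Calls of the Kupffer cell and neutrophil lists were less stable (medians 0.48 and 0.50, camera adjusted p = 0.0145 and 0.0195). The Kupffer cell call ended without young 4 (0.139, median 0.24) or aged 3 (0.0844). The neutrophil call ended without young 5 (0.0911), aged 3 (0.0621) or aged 5 (0.0504) and with quantile normalization (0.0524). The 12 erythroid genes were called lower (median −0.15, camera adjusted p = 0.0334, and adjusted p = 0.622 with an estimated correlation). This call ended without aged 3 (0.101), aged 5 (0.25), young 2 (0.115), young 3 (0.076), young 4 (0.0628) and young 5 (0.055), and with library weights (0.127), quantile normalization (0.0845), no filter (0.168) or a filter at 5 TPM (0.152). It also ended after rescaling without mitochondrial and haemoglobin genes (0.104) and without young 4, aged 5 and treated 1 together (0.276). The median was −0.26 without aged 2, −0.07 without aged 5, −0.06 without young 2 and −0.24 without young 4, and none of these genes passed alone. Globin genes held 0.2 ± 0.0694% of TPM in aged and 0.245 ± 0.104% in young livers.

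Of 27 liver genes with higher expression in females, 9 rose and none fell, and adjusted over the list alone 12 rose and 2 fell. The list was called higher by camera (median 0.58, adjusted p = 1.5e-08, and adjusted p = 0.391 with an estimated correlation) and was the only list called by fry in this comparison (adjusted p = 0.00573). Besides A1bg, Cyp3a44 and Cyp3a16, the sulfotransferase gene Sult2a2 rose from 428 ± 206 to 1101 ± 185 TPM. Of 54 genes of cytochrome P450 and drug metabolism 4 rose and 1 fell, and adjusted over the list alone 5 rose and 8 fell (median −0.13, camera adjusted p = 0.0151, and adjusted p = 0.622 with an estimated correlation). Among them Cyp3a41a rose by 2.85. The list call ended without young 4 (adjusted p = 0.54, median −0.21), without aged 5 (0.2, median −0.04), with quantile normalization (0.325), with library weights (0.363), with a filter at 5 TPM (0.0504) and without young 4, aged 5 and treated 1 together (0.877). The median was −0.06, −0.05 and −0.07 without young 1, 3 and 5. Of 21 genes with higher expression in males, 2 rose and 2 fell, and adjusted over the list alone 5 rose and 7 fell. Mup17 and Mup1 rose, while Cyp2d9 and Egfr, a growth factor receptor gene, fell. This list was not called (camera adjusted p = 0.0716), and its median of −0.06 and mean of 0.20 differ in sign. The calls of Mup1 and Egfr ended in 7 and 10 of 15 fits without 1 library (highest adjusted p 0.0635 and 0.128). Col15a1, a basement membrane collagen gene among the stellate cell and fibroblast markers, rose by 1.38, and the list of 24 was not called (camera adjusted p = 0.322).

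Genes of hepatocyte function were lower as groups, by small amounts. The 23 hepatocyte markers had a median of −0.20 (camera adjusted p = 4.29e-07, and adjusted p = 0.195 with an estimated correlation). None passed alone, and 3 fell adjusted over the list alone. Apoa1, the main apolipoprotein of HDL, stood at 9268 ± 2194 against 14418 ± 3318 TPM. Cyp2e1 stood at 2294 ± 563 against 4316 ± 1061 TPM. Cyp3a11, a xenobiotic-metabolizing P450, stood at 113 ± 77.1 against 1607 ± 436 TPM (log2 difference −4.18, adjusted p = 0.125). It passed without treated 1, where it was at 0.9 TPM (adjusted p = 0.00254). The 26 pericentral genes had a median of −0.23 (camera adjusted p = 3.76e-06, and adjusted p = 0.414 with an estimated correlation), with none past the test alone and 4 lower adjusted over the list alone. Without aged 1 the pericentral median was −0.13 (camera adjusted p = 1.23e-05). The 21 cell cycle genes all had higher means (median 0.48, camera adjusted p = 0.000154, and adjusted p = 0.622 with an estimated correlation), and none passed alone or adjusted over the list alone. Aged 5 carried this call. Its mean over the list was 3.55 on the log2 scale, against 1.53 to 1.76 in the other aged and 1.33 to 1.62 in the young libraries, and without it the median was 0.13 (adjusted p = 0.219). With a filter at 5 TPM the adjusted p was 0.0724, and 0.126 without young 4, aged 5 and treated 1 together. The filter at 1 TPM used the mean over all libraries, so high values in aged 5 could bring genes into this list. Over all 47 lists camera called 25, 13 higher and 12 lower, and none was called with an estimated correlation.

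**Figure D3:**
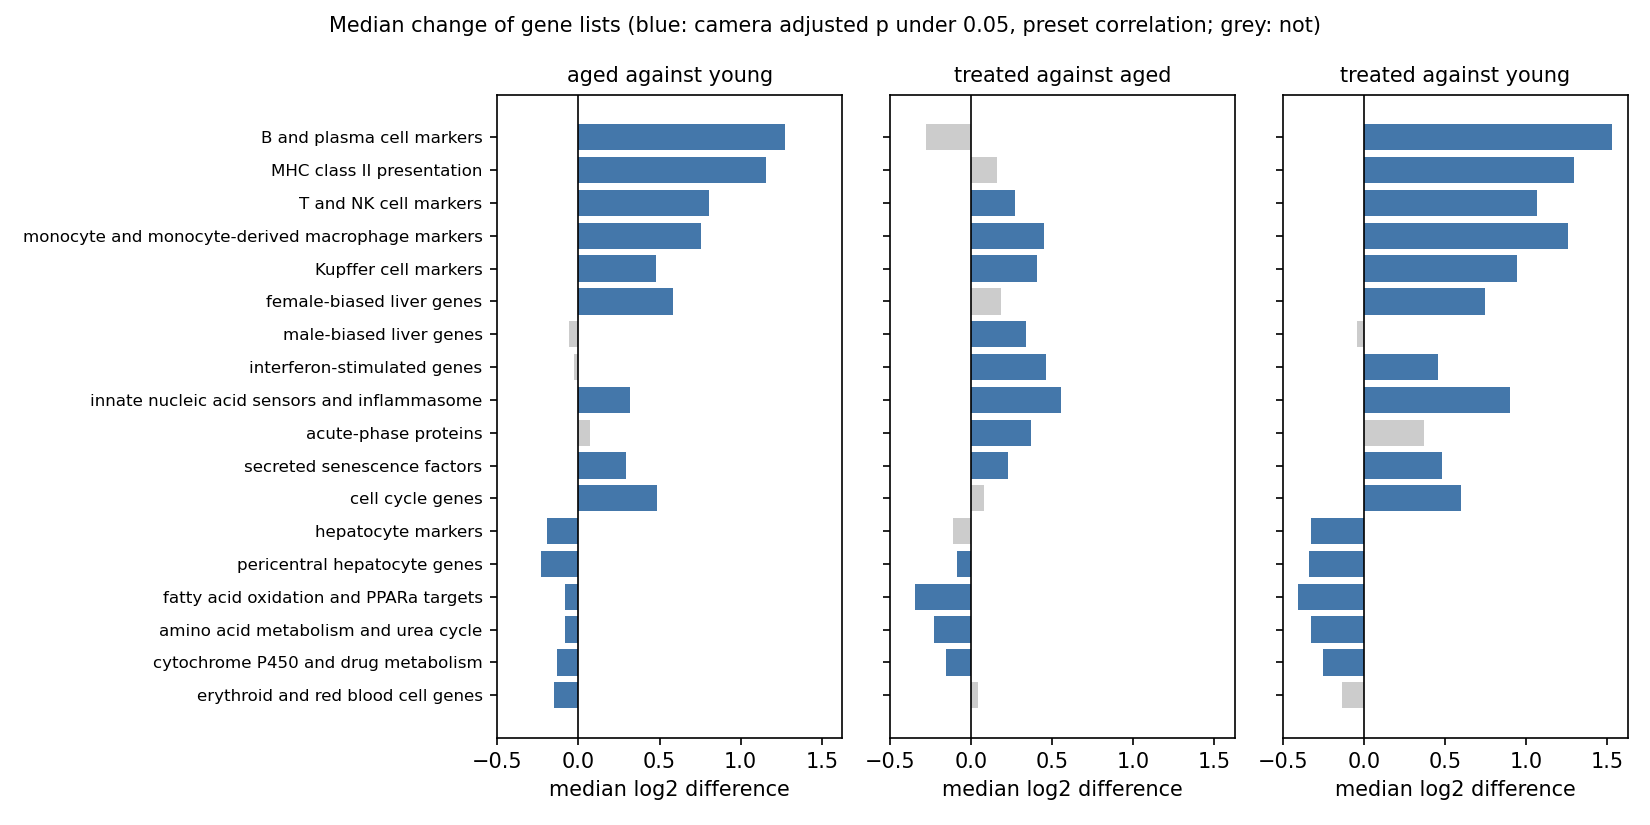
Median log2 difference of 18 gene lists on the x axis, in each of the 3 comparisons. Blue bars mark lists called by camera with a preset correlation and grey bars lists not called. None of these calls held with an estimated correlation. The median of the B and plasma cell markers was 1.27 in aged against young and 1.53 in treated against young livers, the latter 0.86 without treated 4.

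Treated livers differed from aged livers in 1 called gene. This was Gm42605, a predicted gene that falls outside the naming rule and was named after its values were seen. It stood at 14.7 ± 3.44 TPM in treated livers (8.86 to 17.0 in the 5 libraries), was listed at 0 in all 5 aged libraries, and in young livers reached 0.46 TPM in 1 library and was listed at 0 in the other 4 (limma adjusted p = 1.52e-09 against aged livers). In GENCODE M21 it is an unspliced model inside the gene Fras1 on the same strand, so unspliced Fras1 reads could map to it, and Fras1 itself stood at 0.53 TPM or less in every library. The next smallest adjusted p was 0.404. An unadjusted p under 0.05 was found for 537 genes, against 608.4 by chance, and this count lay on either side of chance in other fits. It was 265 without treated 2, 321 without aged 3, 349 without treated 5, 356 without aged 1, 861 without young 4 and 991 without treated 4. It was 807 with quantile normalization, 863 in the fit of these groups alone, 2026 with library weights and 1451 without young 4, aged 5 and treated 1 together. Without aged 3 a further gene, the immunoglobulin segment Ighv1-22, was called lower (adjusted p = 0.0367), and without treated 5 the receptor gene Epha5 was called higher (adjusted p = 0.0348).

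No gene called for age was called between treated and aged livers. Cdkn2a was at 5.76 ± 5.28 TPM in treated and 5.60 ± 5.04 in aged livers (log2 difference −0.03, SE 0.44, adjusted p = 0.996). Treated 5 was at 14.8 TPM. Cdkn1a was at 24.5 ± 11.2 TPM (log2 difference 0.20), Glb1 at 10.3 ± 1.70 (−0.05) and Lmnb1 at 2.81 ± 0.833 (−0.45), with an adjusted p of 0.925 or more for each. Without aged 5 the log2 difference of Lmnb1 was −0.08. Neither the markers expected to rise nor those expected to fall with senescence were called (camera adjusted p = 0.536 and 0.786). A1bg stood at 3405 ± 878 TPM, Cyp3a44 at 464 ± 79.3 and Ighm at 604 ± 866. Mup15 stood at 3407 ± 5406 TPM in treated and 1024 ± 726 in aged livers (log2 difference 0.96, adjusted p = 0.925), with treated 1 at 13056.5 TPM and the other treated libraries at 503 to 1380.04. Of the falls with age, Enho stood at 20.3 ± 8.05 TPM in treated livers, between the aged and young means (log2 difference from aged livers 0.88, adjusted p = 0.925). Of the 132 genes called for age, 67 differed from aged livers toward young and 65 away from it. The median log2 difference toward young was 0.00777. With an unadjusted limma p under 0.05, 15 moved toward young and 6 away. The shared aged libraries favour differences toward young.

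Some lists of inflammation were called higher and some of metabolism lower in treated than in aged livers, although no member of any list passed the test over all genes. Complement and coagulation (camera adjusted p = 0.651) and MHC class I and class II presentation (0.171 and 0.498) were not called, and neither were cholesterol synthesis (0.52), fatty acid and triglyceride synthesis (0.078) and bile acid synthesis and transport (0.734). All 40 interferon-stimulated genes had higher means, with a median of 0.46 (camera adjusted p = 1.04e-13, and adjusted p = 0.602 with an estimated correlation). None rose adjusted over the list alone. The higher values were mostly in 3 treated libraries. Treated 2, 3 and 5 had means over the list of 4.33, 3.87 and 3.94 on the log2 scale, while treated 1 at 3.03 lay inside the aged range of 2.98 to 3.45 and treated 4 at 3.46 just above it. The antiviral gene Oas1g stood at 3.33 ± 1.84 against 0.984 ± 0.567 TPM, the guanylate-binding protein gene Gbp3 at 8.85 ± 4.30 against 3.93 ± 0.955 and Rtp4 at 26.4 ± 8.79 against 16.2 ± 2.89. Among 18 genes of nucleic acid sensing and the inflammasome, 4 rose adjusted over the list alone (median 0.55, camera adjusted p = 3.35e-09, and adjusted p = 0.602 with an estimated correlation). Ifi204, an interferon-inducible DNA sensor, stood at 7.40 ± 2.26 against 3.41 ± 0.978 TPM and Mndal at 8.16 ± 2.97 against 4.20 ± 1.53. Monocyte and macrophage markers were higher in 23 of 24 means (median 0.45, camera adjusted p = 1.03e-06, and adjusted p = 0.602 with an estimated correlation). The Fc receptor gene Fcgr1 stood at 8.73 ± 4.83 against 4.11 ± 1.80 TPM, and Clec7a, a fungal glucan receptor gene, at 10.6 ± 4.15 against 5.96 ± 3.77. The 20 Kupffer cell markers had a median of 0.41 (camera adjusted p = 0.00241, and adjusted p = 0.74 with an estimated correlation), with the complement receptor gene Vsig4 at 84.0 ± 39.5 against 48.4 ± 13.5 TPM and the lectin gene Clec4f at 194 ± 78.5 against 125 ± 24.2. The 27 acute-phase genes had a median of 0.37 (camera adjusted p = 0.000597, and adjusted p = 0.74 with an estimated correlation), with the ceruloplasmin gene Cp at 1324 ± 629 against 795 ± 264 TPM and Apcs at 416 ± 309.5 against 186 ± 79.8. The 10 neutrophil markers had a median of 0.42 (camera adjusted p = 0.000878, and adjusted p = 0.602 with an estimated correlation), with S100a8 at 10.8 ± 9.09 against 3.79 ± 1.36 TPM. No member of these 4 lists rose adjusted over the list alone. The 40 secreted senescence factors were also called higher in treated than in aged livers (median 0.23, camera adjusted p = 0.00384, and adjusted p = 0.74 with an estimated correlation), and none passed adjusted over the list alone. Ccl6 stood at 28.5 ± 14.7 against 12.7 ± 4.76 TPM and Igfbp5 at 4.21 ± 2.27 against 6.89 ± 0.927. That call ended without treated 4 (adjusted p = 0.0893), and without treated 5 the median was 0.14. Treated 1 was the lowest treated library in each of these called lists. Its means over the monocyte, Kupffer cell, neutrophil and secreted factor lists, at 2.98, 4.54, 2.55 and 2.97 on the log2 scale, lay below those of all aged libraries. Without treated 5 the acute-phase and Kupffer cell lists were not called (adjusted p = 0.21 and 0.28, medians 0.14 and 0.11), and the median of the monocyte markers was 0.25. Without treated 1 these medians were 0.57, 0.74 and 0.79. The median of the interferon-stimulated genes was 0.30 without treated 2. Saa1, an acute-phase gene named after its values were seen, was at 7814 TPM in treated 5, 2940.1 in treated 4 and 9029.85 in aged 5, and at 968 or less in the other 12 libraries.

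Fatty acid oxidation genes and targets of the lipid sensor PPARa were lower in 34 of 38 means (median −0.35, camera adjusted p = 1.69e-10, and adjusted p = 0.602 with an estimated correlation). Treated 3 and 4, with means over the list of 6.12 and 6.44 on the log2 scale, lay inside the aged range of 6.01 to 6.58. Acaa1b and Ehhadh, of peroxisomal fatty acid oxidation, stood at 290.5 ± 123 against 594 ± 169 TPM and 105 ± 31.7 against 159 ± 38.3. Cyp4a10, a fatty acid hydroxylase, stood at 149.5 ± 59.1 against 245 ± 66.4 TPM. Genes of amino acid metabolism and the urea cycle had a median of −0.23 (camera adjusted p = 6.82e-07, and adjusted p = 0.602 with an estimated correlation), with Ahcy, the hydrolase of S-adenosylhomocysteine, at 873 ± 155 against 1173 ± 171 TPM. Without aged 3 the latter median was −0.14. Adjusted over each list alone, no member fell. Hepatocyte markers were lower in 17 of 23 means and not called (median −0.11, camera adjusted p = 0.0574). Periportal genes were called lower (median −0.21, camera adjusted p = 0.00965, and adjusted p = 0.74 with an estimated correlation). That call ended without aged 1 (0.102), treated 2 (0.115) or treated 5 (0.087) and with quantile normalization (0.123), and the median was −0.13 without aged 3 and −0.09 without aged 4. Pericentral genes were called lower (median −0.09, camera adjusted p = 0.0487, and adjusted p = 0.74 with an estimated correlation), and this call ended in 9 of 15 fits without 1 library (highest adjusted p 0.383, without treated 5). The median ranged from −0.18 without treated 3 to −0.0003 without treated 5, and was −0.13, −0.14 and −0.15 without aged 1, aged 5 and treated 2. Male-biased liver genes were called higher (median 0.34, camera adjusted p = 0.0038, and adjusted p = 0.602 with an estimated correlation), and none rose adjusted over the list alone. Serpina1e, a protease inhibitor of this list, stood at 268 ± 177 against 67.4 ± 25 TPM. This call ended without treated 1 (adjusted p = 0.0627), in which Mup genes held 11.8% of TPM against 1.95% to 2.74% in the other treated libraries. It also ended with no filter (0.0675) and without young 4, aged 5 and treated 1 together (0.0776). In all, camera called 20 of 47 lists, 10 in each direction, 13 without treated 5 and 36 without young 4, aged 5 and treated 1. None was called with an estimated correlation (smallest adjusted p 0.602) or by fry.

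No age-changed gene was called by limma as moved back by treatment, and none could be, since Gm42605, the only gene called between treated and aged livers, was not called for age (log2 difference −0.11). With the aged libraries split between the comparisons, at most 1 gene moved back over 10 splits. Without aged 3, 1 gene (Ighv1-22) moved back. Across genes, the age and treatment changes had a correlation of −0.166 and a covariance of −0.0296. Simulated groups with no effect gave a mean correlation of −0.494 and a mean covariance of −0.05 (SD 0.0376, range −0.148 to 0.0299), since both changes hold the aged libraries. Those groups held no age effect either, which makes the spread of the age change smaller. The correlations are therefore not comparable, and only the covariances can be set side by side. With the aged libraries split between the changes, the covariance averaged 0.0146 (range −0.0267 to 0.0746 over 20 splits). Genes are not independent replicates, and no p is given.

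The share of the age difference regained by treated livers had a median of −0.0935 over 100 splits (range −0.667 to 0.0651), where 0 is the level of held-out aged and 1 that of held-out young libraries. In a comparison with aged libraries held out of both steps, the 5 treated libraries had a mean share of −0.0809 ± 0.12 and the 5 aged libraries −0.0676 ± 0.226 (difference −0.0133, two-sided permutation p = 0.921). The nominal 95% interval of the difference, by inverting that test, ran from −0.255 to 0.265. Both are approximate, since the aged values depend on one another and came from fewer fits than the treated values. Aged 5, at −0.429, set the aged mean. The other aged libraries lay at −0.104 to 0.18. With only the finished value of aged 5 deleted, the aged mean was 0.0227 and the difference −0.104 (permutation p = 0.238). Aged 5 still entered the gene selection and the 0 level for the other libraries, so these values are not free of it. With aged 5 removed from all steps, the median share regained by treated livers was −0.128. The difference ranged up to 0.0486, with the value of aged 3 deleted.

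**Figure D4:**
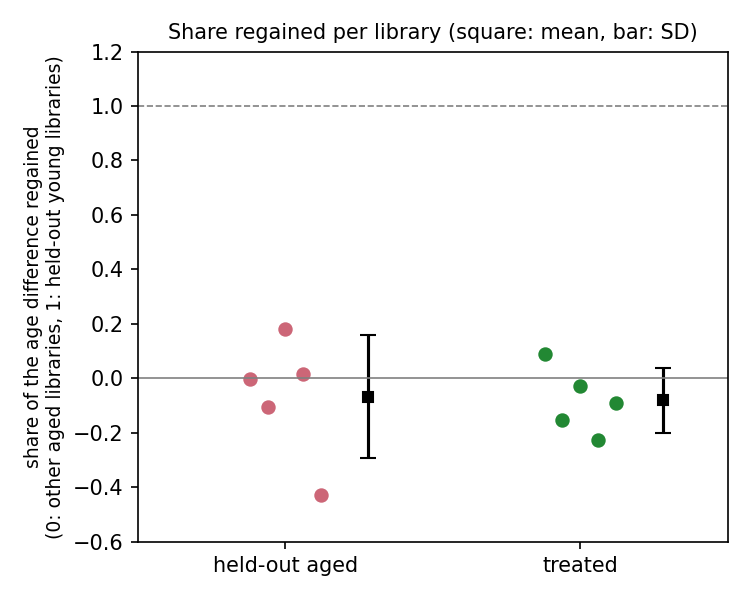
Share of the age difference regained per library on the y axis, for the 5 held-out aged and the 5 treated libraries. Points are libraries, squares are means and bars are SD. Both groups centre near 0, at −0.0676 for aged (0.0227 with the value of aged 5 deleted) and −0.0809 for treated livers, far from the young level of 1.

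Several of the largest rises from young to treated livers were in genes that also rose in aged livers. A1bg was at 3405 ± 878 TPM against 20.6 ± 13.0 (log2 change 7.48, adjusted p = 9.36e-08). Mup15 rose by 8.97, Mup17 by 7.38, Cyp3a44 by 6.07, Mup19 by 6.04, Cyp3a16 by 5.92, Ighm by 5.83 and Mup13 by 5.62. Cdkn2a rose by 2.33 (adjusted p = 0.00895, and 0.0999 with a pseudocount of 5). The largest falls were in Cyp3a11, from 1607 ± 436 to 116 ± 90.8 TPM (log2 change −4.83), and in Cyp2b13, a P450 of female liver, from 280.5 ± 101 to 19.5 ± 20.9 TPM (−4.46). Cyp2d9 fell by 3.95, the histone gene H3c14 by 2.27, Ociad2 by 2.09 and Hsd3b3 by 1.93. Eif4ebp3 (log2 change −1.94) and the protease inhibitor gene Mug1 (−1.94) also fell. Cdkn1a, Glb1 and Lmnb1 did not pass (log2 differences −0.48, 0.04 and 0.18).

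In all, 354 genes were called by limma, 265 higher and 89 lower, and 90 of the rises and 15 of the falls were shared with aged against young, with none in opposite directions. The young libraries enter both comparisons. With these split between the comparisons, 29 to 44 rises and 2 to 5 falls were shared over 10 splits. The split fits held fewer young libraries, which limits how many genes could be shared. They called 52 to 123 genes for aged and 40 to 1504 for treated against young. Independent calls in the full fits would share 2.46 rises and 0.139 falls. Simulated groups without effects shared 0 of each, but such groups are expected to give few calls that could be shared. That 0 therefore cannot show how much of the sharing comes from the young libraries. The covariance of both changes was 0.231, against 0.0462 in simulated groups without effects and 0.18 with the young libraries split. The count of 354 was unstable. It was 1192 without young 4 (488 higher, 704 lower), 599 without treated 1, 218, 211 and 209 without young 2, 3 and 5, and 183 and 194 without treated 2 and 5. Without young 4, aged 5 and treated 1 together it was 1458, of which 963 were higher. Quantile normalization, which moved the median of all genes by −0.13 on the log2 scale, gave 252 higher and 322 lower genes, and median-ratio scaling 356 higher and 242 lower. Leaving out 1 library ended the calls of H3c14 and Cyp3a11 in 9 and 6 of 15 cases (highest adjusted p 0.114 and 0.0897).

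Of the 24 monocyte and macrophage markers 8 rose, and 22 rose adjusted over the list alone (median 1.26, camera adjusted p = 3.29e-14, and adjusted p = 0.331 with an estimated correlation). Trem2 reached 8.45 ± 3.35 TPM against 1.16 ± 0.756 in young livers, and Clec7a 10.6 ± 4.15 against 2.68 ± 1.15. Of 40 interferon-stimulated genes 4 rose, and 13 rose adjusted over the list alone (median 0.46, camera adjusted p = 3.24e-06, and adjusted p = 0.578 with an estimated correlation). Their median was 0.25 without treated 2. Ifi27 rose by 1.09, Rtp4 by 1.11 and Gbp3 by 1.2. Of 18 nucleic acid sensing genes 5 rose, among them Ifi204 and Mndal, and 14 rose adjusted over the list alone (median 0.90, camera adjusted p = 3.88e-09, and adjusted p = 0.331 with an estimated correlation). Of 40 secreted senescence factors 4 rose and 1 fell, and adjusted over the list alone 14 rose and 2 fell (median 0.48, camera adjusted p = 7.92e-05, and adjusted p = 0.457 with an estimated correlation). The markers expected to fall with senescence were called higher here as well (median 0.42, camera adjusted p = 0.0413, and adjusted p = 0.649 with an estimated correlation), and not without young 1 (0.07), young 4 (0.0581) or treated 4 (0.0985) or with a pseudocount of 5 (0.0725). None passed alone or adjusted over the list alone. Those expected to rise were not called (adjusted p = 0.0663). Of the secreted factors, the chemokine genes Ccl6 and Cxcl14 rose by 1.58 and 0.93, and Igfbp2 fell by 1.03. Of 26 pericentral genes 4 fell, and 8 fell adjusted over the list alone (median −0.34, camera adjusted p = 1.2e-06, and adjusted p = 0.331 with an estimated correlation). Their median was −0.20 without young 5. Cyp2e1 reached 1793 ± 678 TPM against 4316 ± 1061, and Cyp1a2 214 ± 41.8 against 457 ± 152. Of 38 fatty acid oxidation genes 4 fell, and adjusted over the list alone 13 fell and 1 rose (median −0.40, camera adjusted p = 7.63e-11, and adjusted p = 0.353 with an estimated correlation). The fatty acid hydroxylase genes Cyp4a10 (log2 change −1.88) and Cyp4a14 (−2.58) fell. Of 19 T and NK cell markers 2 rose, among them the granzyme gene Gzmb (log2 change 1.52), and 10 rose adjusted over the list alone (median 1.07, camera adjusted p = 5.76e-07, and adjusted p = 0.462 with an estimated correlation). Treated 1, with a mean over the list of 0.956 on the log2 scale, lay inside the young range of 0.90 to 1.08, and the other treated libraries lay at 2.34 to 2.61. Treated 1 also lay inside the young range for the Kupffer cell, secreted factor, interferon-stimulated and nucleic acid sensing lists. Of 20 Kupffer cell markers 2 rose and 1 fell, and adjusted over the list alone 11 rose and 1 fell (median 0.95, camera adjusted p = 6.07e-05, and adjusted p = 0.578 with an estimated correlation). Vsig4 rose by 1.43 and Clec4f by 1.11. Of 48 nuclear genes of oxidative phosphorylation only Atp5b, a subunit of ATP synthase, fell (log2 change −0.88), also adjusted over the list alone (median −0.20, camera adjusted p = 5.09e-07, and adjusted p = 0.339 with an estimated correlation). Single left-out libraries ended the calls of Gzmb, Clec4f and Atp5b in 7, 5 and 9 of 15 cases (highest adjusted p 0.0966, 0.0826 and 0.115). They also ended the calls of Clec7a, Gbp3 and Cyp4a14 in 3, 4 and 6 of 15 cases (highest adjusted p 0.06, 0.0797 and 0.0897). Camera called 26 of 47 lists, none with an estimated correlation, and fry called 5.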

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

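The tests of whole-family sums, of a lower hepatocyte share and of newborn-like livers were chosen after the results were seen, and the other tests in this part before. The rule by which the power test is read was changed after its result was seen, and the percentages of genes beside it were added then.

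Of 222 groups of 5 libraries checked for a single value far from the other 4, 20 stood out, and chance gives about 1 in 20 groups, or 11.1. Of these, 8 were in treated 1. In treated 1, Mup genes held 11.8% of TPM, with Mup19 at 18366 TPM, Mup1 at 641 and Mup13 at 50869.9 TPM. Cdh1 was also high there (11.4 TPM), and Cd74 (142 TPM), Ccl5 (4.94) and Gm42605 (8.86) were low for the group. In aged 5, Cdkn2a was at 14.6 and Lyz2 at 561 TPM, and Ehhadh was low at 93.5 TPM. In young 4, Mup1 was high at 4.93 TPM and Mug1 low at 344 TPM. In young 5, Apoa1 was high at 20148 and Cyp2b13 at 459 TPM. Treated 4 had Ighm at 2153 TPM and treated 3 had Eif4ebp3 at 12.6 TPM. Gm42605 reached 0.46 TPM in young 3. Fras1 was at 0.53 TPM in aged 4 and 0.12 in treated 5.

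Chance regrouping of the libraries is excluded for the contrasts with young livers. Of 100 splits of the 10 aged and young libraries, 1, the real one, reached 132 genes, and the highest other gave 5. For treated against young, 1 of 100 splits reached 354, the real one, and the highest other gave 11. For treated against aged, 10 of 100 splits gave 1 gene or more and the highest other gave 150, so chance is not excluded for the count of 1. That split set aged 5 with treated 2, 3, 4 and 5 against aged 1, 2, 3 and 4 with treated 1, and a count of its size points to a structure among the samples. It amounts to an exchange of aged 5 and treated 1, and no test was run that tells an exchange from another structure. On Gm42605 both libraries went with their labels, at 0 TPM in aged 5 and 8.86 in treated 1.

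Many female-biased and Mup genes were higher in aged than in young livers, with exceptions, since 19 of 27 female-biased genes had higher means and Cyp2b13 stood at 46.8 ± 40.7 against 280.5 ± 101 TPM, and 9 Mup genes were called. Reads moved between near-identical copies leave family sums as they are, yet the Mup and Sult2a sums were higher by 2.33 (SE 0.66) and 1.59 (SE 0.34) on the log2 scale, while for the Cyp3a genes, whose sum of 11 members differed by 0.59 (SE 0.31), moved reads cannot be told apart from a change, since that difference lies within 2 SE. A lower hepatocyte share would lower hepatocyte genes alike, yet the median of the female-biased list lay 0.78 above that of the hepatocyte markers. Newborn-like livers in the young group would show abundant Afp, which stood at 0.822 ± 0.281 TPM in young livers. The detected newborn genes had a median log2 difference of 0.13, but averaged at most 1.6 TPM in young livers. Values this low leave little room for a fall, so that median decides nothing. A difference in sexual maturity or hormone state that comes with age may underlie the pattern, as a hypothesis that was not tested, since ages are not given in the sources used here.

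Gm42605 was at 8.86 TPM or more in the 5 treated libraries and listed at 0 in all controls but young 3 (0.46 TPM). Genomic DNA or unspliced RNA would raise unspliced models in general. Of 49 others of that kind, 36 had higher and 13 lower means in treated than in aged livers. Their median log2 difference was 0.22, with quartiles of −0.01 and 0.55, against −0.0005 over all genes. None was called, but Gm42605 was the only gene called at all. A small general rise is therefore not excluded, though its median lay far below the log2 difference of 3.94 in Gm42605. Treated mice from another colony would be likely to differ in several genes with values in all of one group and none or nearly none in the other, and apart from Gm42605 there were 0 such genes between treated and aged livers (at least 1 TPM in all 5 against at most 0.1 in all 5). Between aged and young livers there were 5, of which 3 are immunoglobulin variable segments, and between treated and young livers there was 1. The 0 argues against a colony that differs in several such genes, but not against a close one. How many such genes another colony would give is unknown. Another colony is therefore excluded neither for the treated mice nor for the age contrast. A local variant near Gm42605 and an effect of the treatment stay open and were not tested.

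Only 1 gene passed the threshold between treated and aged livers. Leaving out the inflamed library aged 5 did not raise the count, with 1 gene called without it. That count cannot exclude that aged 5 hides differences, since power was low for changes in few genes, as given below. Camera called 29 lists without aged 5 and 20 with it. Too little power for 2-fold changes cannot be told apart from no change. The simulations recovered 70.0% of genes changed by 1 on the log2 scale, but with 200 genes changed and independent noise for each gene. By the standard errors of all genes, a measured change of 1 would pass in 67.9% of genes if 200 passed and in 6.16% if 1 passed. The bound of 50% therefore did not cover a change in few genes. A partial return of the age pattern spread over many genes cannot be told apart from none either. The difference in share regained from held-out aged livers was −0.0133 (−0.104 with the value of aged 5 deleted), with an approximate interval up to 0.265.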

How the results depend on the processing

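Leaving out young 4, aged 5 and treated 1 together was chosen after seeing the data. Of the genes named in the text, 16 of 27 called for aged against young and 33 of 48 for treated against young kept their call in all alternatives that tested them. None reversed. The filter at 5 TPM did not test some of these genes, among them Ociad2, Trem2, Ifi204 and Cxcl14. The minimum change of 1 on the log2 scale was not applied to these calls. With a filter at 5 TPM, which tests fewer genes and drops Gm42605, the counts were 76 for aged against young, 0 for treated against aged and 217 for treated against young, with 16 and 13 lists called for the first 2 comparisons. Without a filter, treated against young gave 188 genes. Quantile normalization gave 574 genes there and 13 lists for treated against aged, median-ratio scaling gave 598 genes, and library weights gave 1538 genes there and 244 for aged against young. The added alternative gave 1458 genes and 36 lists in those comparisons. The estimated correlation ended all list calls (0, 0 and 0), and fry called 1, 0 and 5 lists. The covariance was −0.0919 with a pseudocount of 0.1, and the share regained was −0.039 with that pseudocount and −0.151 with a pseudocount of 5. The causes were not tested. Leaving out 1 library gave 79 to 165 genes for aged against young, 1 to 2 for treated against aged, 183 to 1192 for treated against young, 0 to 1 moved back, a covariance of −0.0523 to −0.012, a share of −0.128 to −0.04, and 18 to 28, 13 to 29 and 24 to 34 lists. No pairing of libraries by replicate number was evident, and the labels state none. Same-numbered libraries had correlations from −0.249 to 0.309, over 0.1 in 4 of 15 pairs, and 4 of 15 correlated best with their own number. The replicate block gave 116, 1 and 373 genes. Depth is unknown, so its limit on low genes cannot be given. The share has no value under the block, weights, 2-group and moderation alternatives, which do not enter it.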

Other observations

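Several lists not described so far were called in aged against young livers by camera with a preset correlation. Lower were genes of amino acid metabolism (median −0.08, adjusted p = 2.76e-05), complement and coagulation (−0.07, 0.000218) and bile acids (−0.26, 0.000217). No single left-out library ended these calls, but the complement median was 0.003 without young 3. The bile acid call ended without young 4, aged 5 and treated 1 together (0.0833). Ribosomal protein genes were higher in 49 of 55 means (median 0.15, adjusted p = 0.0299, and adjusted p = 0.776 with an estimated correlation). This call ended with median-ratio scaling (0.172), with a pseudocount of 0.1 (0.051) and without aged 2 (0.702), aged 5 (0.426), young 1 (0.117), young 2 (0.236), young 3 (0.148) or young 5 (0.0612), and the median was 0.09 without aged 2 and 0.08 without aged 5. Fatty acid and triglyceride synthesis genes were higher in 22 of 25 means (median 0.25, adjusted p = 0.00457, and adjusted p = 0.622 with an estimated correlation). This call ended without aged 4 (0.0514, median 0.15) or young 2 (0.0555), and the median was 0.08 without young 4 and 0.41 without young 5. Genes of nuclear-encoded oxidative phosphorylation were lower in 37 of 48 means (median −0.08, adjusted p = 3.78e-05, and adjusted p = 0.622 with an estimated correlation). This call ended without young 4 (0.234), with library weights (0.289) and without young 4, aged 5 and treated 1 together (0.938), and the median was −0.04 without young 4 or aged 5. Nucleic acid sensing genes were called higher (median 0.32, adjusted p = 0.00467) and fatty acid oxidation genes lower (median −0.08, adjusted p = 0.00457). Both calls ended without aged 5 (0.0793 and 0.426). In treated against aged livers, genes of the unfolded protein response were higher in 25 of 28 means (median 0.15, adjusted p = 0.00618, and adjusted p = 0.74 with an estimated correlation). This call ended without treated 5 (0.323, median 0.06) or aged 2 (0.0914), and the median was 0.30 without aged 5 and 0.25 without treated 1. Targets of the oxidative stress factor NRF2 were lower in 28 of 35 means (median −0.17, adjusted p = 0.00241, and adjusted p = 0.602 with an estimated correlation). That call ended with quantile normalization (0.0597), and the median was −0.11 without aged 3 and −0.12 without treated 1. Gclc, which makes the first enzyme of glutathione synthesis, stood at 50 ± 7.65 against 77.2 ± 10.5 TPM and did not pass (adjusted p = 0.925).

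Mitochondrially encoded genes held 3.58% to 10.98% of TPM in young livers, 5.997% to 9.46% in aged and 6.77% to 8.76% in treated livers. The 8 Sult2a genes together stood at 684 ± 328 TPM in young, 1894 ± 335 in aged and 2123 ± 270.1 in treated livers, and the 11 Cyp3a genes at 2392 ± 936, 3464 ± 955 and 4702 ± 1019 TPM.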
